A study of Homo sapiens with 28 samples.

How the data were processed

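RNA sequencing data came from CD8+ T cells sorted by flow cytometry from the blood of 14 donors, 7 with ME (myalgic encephalomyelitis, also called chronic fatigue syndrome) and 7 healthy controls (HC) with a sedentary lifestyle. Each donor gave 1 library of naive cells (positive for CD45RA and CCR7) and 1 library of antigen-experienced cells (negative for CD45RA, with or without CCR7), which makes 28 libraries in 4 groups of 7. Per the labels' protocols, T cells were enriched with CD3 beads, dead and CD56-positive cells were excluded in the sort, and poly(A)-selected, strand-marking libraries were made from 25 ng of RNA and sequenced as read pairs of 150 bases. The study also made chromatin accessibility libraries, which were not used here.

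The deposited values are raw read counts per Ensembl gene, with no normalization, for 58884 gene IDs. Per the submitters' processing notes, the authors trimmed reads with Trim Galore 0.6 and aligned them with STAR 2.7 to the human genome build GRCh38. The counting tool, its strand setting and the annotation release are not given in the sources used here. For that reason reads of overlapping antisense genes may not have been told apart, and genes with near-identical copies (CCL4, KLRC1, TRGC1, TRGC2, ribosomal protein genes with processed pseudogenes, and mitochondrially encoded genes with nuclear copies) carry an uncertainty from how reads matching several places were counted. Symbols were matched by gene ID for 58472 IDs in a table of gene names and for 404 more in GENCODE v29, from which coordinates on GRCh38 were taken. XIST, TSIX and the genes of the Y chromosome, 512 IDs holding 0.0464% of all counts, were removed before normalization and are not reported. No pair of libraries was identical, and the highest correlation of log2 CPM between 2 libraries of a group was 0.960 across genes.

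Total counts per library ranged from 10.1 to 24.2 in units of 1e6. Each comparison was tested on counts with the quasi-likelihood F test of edgeR 4.0.16 (robust fit, TMM normalization, filterByExpr on the groups) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors were taken as the log2 fold change divided by the square root of F. The titles hold 2 series of donor codes, called label series A and B here, whose meaning is not given in the sources used here. The titles of series A also carry a further tag, of unstated meaning, that those of series B lack. Series A holds 4 HC and 3 ME donors and series B holds 3 HC and 4 ME donors, and the series entered each model as a covariate. ME and HC donors were compared within naive and within experienced libraries (14 libraries each), experienced and naive libraries were compared within HC and within ME donors (14 each), and the difference of the ME effect between cell subsets was tested as an interaction over all 28. CPM values are means ± SD over the 7 libraries of a group, scaled with TMM within a comparison.

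Gene lists were tested with camera from limma 3.58.1 with a preset inter-gene correlation of 0.01, over 35 lists that held 829 genes, of which 828 were found. The lists comprised 24 cell programs and 11 sets of markers of other cell types, and a list entered a comparison with at least 5 measured members. Camera was repeated with the correlation estimated per list, and fry was run as a test of whether a list's genes move one way. Counts of changed members were made over all genes and adjusted over the list alone. The comparisons, covariates, lists and the rule for named genes were fixed before the data were examined. By that rule the text names, per comparison, the 8 genes with the largest rise and the 8 with the largest fall among those past the threshold with a mean log2 CPM of at least 2, leaving out unnamed genes, pseudogenes, antigen receptor segments and genes of highly variable families (HLA class I and most class II, KIR, and the GSTM1, GSTT1 and UGT2B genes). Where fewer than 8 passed in a direction, the 3 with the smallest p were named and said not to pass. Up to 3 members with the smallest p were named per described list, and PDCD1, TOX, TCF7, CCR7, GZMB and CD8A were always given. For a gene without any count in one group, the fold was computed against a floor of 3 counts over that group's libraries and is a lower bound that covers counting error only.

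The naive and experienced library of a donor share a donor code in the labels, so the samples are paired by person. Columns were matched to libraries by the numbers in the descriptions, and 2 libraries carry numbers out of the run of their cell subset, so their match is less sure. The highest cytotoxic mean of a naive library was 3.15 log2 CPM and the lowest of an experienced library 5.05, so 0 libraries lay on the side of the other subset. As a further check, the deviations of paired libraries from their group means correlated across genes at a median of 0.211, with 12 of the 14 pairs above 0.1 (range 0.0518 to 0.372). The planned fit left the donor out as a block and a second fit kept it. Other alternatives were DESeq2 size factors, no filter on low counts, DESeq2 1.42.0 (Wald test), limma voom with sample quality weights, no series covariate, and each series alone. After seeing the data, fits were added without 2 experienced ME libraries whose descriptions carry an extra letter of unstated meaning ("marked" here), without the 3 experienced libraries with the fewest genes (the same 2 and 1 HC library), without that HC library, and without the naive library with the highest cytotoxic mean. A list's mean log2 CPM per library was also compared between ME and HC by an exact permutation test, two-sided, over all 3432 assignments of donors (smallest possible p 0.000583), with adjustment over 33 lists. This test does not take the label series into account, and the donor splits used below were drawn without regard to it.

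The tests were checked on counts simulated from each comparison's own genes, with 200 genes changed. The share recovered for a 2-fold and a 4-fold change was 78% and 89% in ME vs HC in naive cells (17347 genes), 50% and 87% in ME vs HC in experienced cells (16397 genes), 60% and 91% between subsets in HC (17310 genes), 48% and 87% between subsets in ME (16310 genes), and 34% and 69% for the interaction (21902 genes). Between 4 and 5 unchanged genes were called in each, and no unshifted list. The changed genes were drawn from those with a mean log2 CPM of at least 2, so the shares do not cover weaker genes. Each gene was simulated independently of the others and without donor effects. The check therefore cannot show how often camera calls lists whose genes are correlated, which the splits of donors or libraries below address.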

Results

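The data describe CD8+ T cells, the lymphocytes that kill infected cells, in ME and in health. ME is a chronic illness marked by exhaustion that worsens after exertion. The series title frames the question as whether the CD8+ T cells of patients are shifted toward T cell exhaustion, a state of lasting antigen stimulation in which inhibitory receptors and the factor TOX are raised and effector function declines. Each of the 4 groups (naive HC, naive ME, experienced HC, experienced ME) held 7 libraries from 7 donors. The donors are separate people per the labels, and they are the replicates where ME and HC were compared within a subset. The main fits between subsets and of the interaction treat the 2 libraries of a donor as separate replicates. The fit with donors as a block takes the pairing into account. Total counts per library, in units of 1e6, were 10.1 to 22.8 in naive HC, 14.7 to 22.6 in naive ME, 10.7 to 24.2 in experienced HC and 12.8 to 22.6 in experienced ME. The number of genes with a count was 23287 ± 1532 (SD, n = 7), 23298 ± 3368, 22919 ± 2611 and 21112 ± 3603 in the same order. Mitochondrially encoded genes took a median of 5.69%, 6.09%, 5.23% and 5.96% of counts, with a maximum of 21.2% in 1 experienced ME library.

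Marker genes showed what the sort had collected. CD8A, which encodes a chain of the CD8 co-receptor, stood at 585 ± 127 CPM (SD, n = 7) in naive HC, 718 ± 179 in naive ME, 1040 ± 298 in experienced HC and 982 ± 220 in experienced ME. CD3E, a chain of the T cell receptor complex, stood between 782 ± 118 and 916 ± 56.0 CPM in all groups. CD4, the co-receptor of helper T cells, averaged at most 1.79 CPM in any group. The monocyte genes CD14 and LYZ, the haemoglobin gene HBB and the platelet gene PPBP each averaged under 2 CPM in every group, and TRDC, the constant gene of the delta receptor chain, at most 3.49 CPM. Not all markers of other lymphocytes were low in experienced cells: MS4A1, which encodes CD20, averaged 9.36 ± 4.50 CPM in HC and 21.2 ± 19.9 in ME, and the NK receptor gene KLRF1 11 ± 4.65 and 22.5 ± 11.7. FOXP3, of regulatory T cells, averaged at most 5.17 CPM, the NK gene NCAM1 at most 2.22, and SLC4A10, found on MAIT cells, 155 ± 116 in experienced HC and 120 ± 88.7 in experienced ME. KLRB1, which encodes the receptor CD161 found on MAIT cells, averaged 0.169 ± 0.326 CPM in naive HC and 0.800 ± 0.664 in naive ME, against 122 ± 99.1 in experienced HC and 68.0 ± 38.7 in experienced ME.

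**Figure D1:**
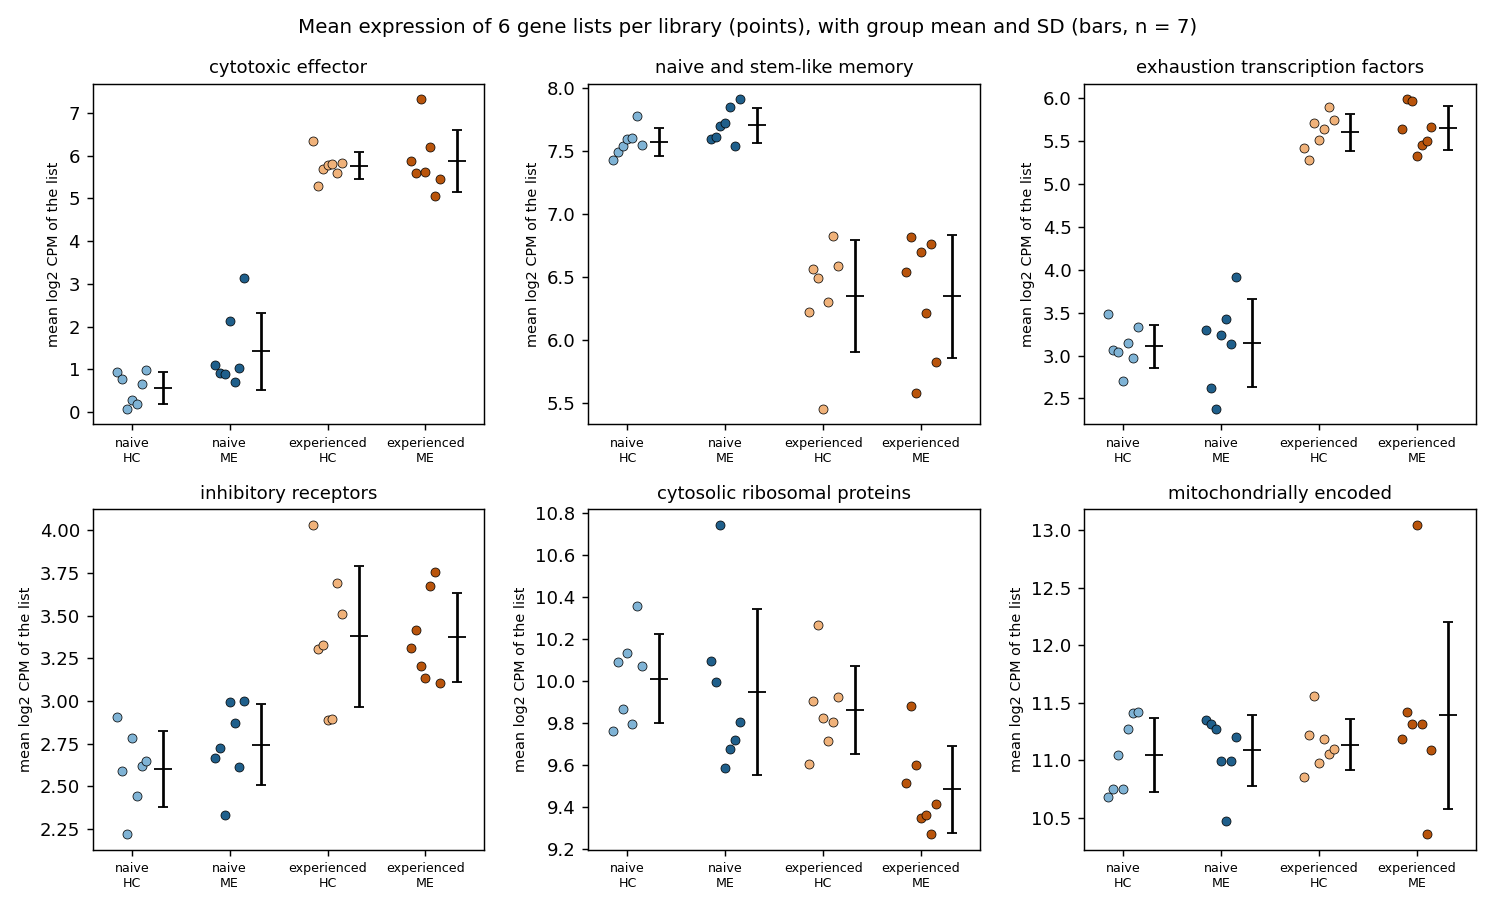
Mean log2 CPM of 6 gene lists (vertical axes) in each of the 28 libraries, grouped by cell subset and donor class, with points for libraries and bars for the group mean and SD (n = 7). The cytotoxic mean was 0.56 ± 0.37 in naive HC, 1.42 ± 0.89 in naive ME, 5.76 ± 0.32 in experienced HC and 5.88 ± 0.73 in experienced ME, and the ribosomal protein mean was 9.86 ± 0.21 in experienced HC and 9.49 ± 0.21 in experienced ME.

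The comparison of experienced with naive cells in HC donors asked what antigen experience adds to a healthy CD8+ T cell. The genes of killing rose steeply: GZMH, GZMB and GNLY, which encode a pair of granzymes and granulysin, were higher by 9.11 ± 1.00, 8.23 ± 1.04 and 7.77 ± 0.98 on the log2 scale (± SE, 7 libraries per subset). CCL4, a chemokine that draws in other leukocytes, had no count in any naive HC library and averaged 10.4 ± 4.57 CPM (SD, n = 7) in experienced cells, at least 438-fold higher against a floor of 3 counts over the naive libraries. KLRB1 rose by 9.24 ± 0.90, the kinase gene LTK by 7.52 ± 1.00, S1PR5, a receptor that guides exit from tissue, by 7.40 ± 0.74, and the cytokine gene TNF by 7.37 ± 0.89. Among the genes that fell most were REG4, a secreted lectin (-7.47 ± 0.79), the adhesion gene NRCAM (-5.93 ± 0.46), the growth factor gene CLEC11A (-5.96 ± 0.84), the Wnt antagonist SFRP5 (-5.61 ± 0.81), the BMP antagonist NOG (-4.87 ± 0.88), the keratin gene KRT73 (-5.24 ± 1.32), the metalloproteinase MMP28 (-5.00 ± 0.97) and the phosphatase PTPRK (-4.99 ± 1.02). All of these named genes moved the same way in 7 of 7 donors. With limma voom the folds of GZMB, GNLY, KLRB1, LTK and KRT73 stayed large but did not pass (adjusted p = 0.147, 0.180, 0.0548, 0.0725 and 0.107), and these were their highest over the alternatives, with lowest values of 3.92e-14, 2.58e-25, 2.82e-13, 2.55e-07 and 2.34e-06. In total 3750 of 17310 genes passed (21.7%), with 1967 higher, 1783 lower and 1600 changed by more than 2-fold. Within label series A alone 1983 genes passed and within series B 1528.

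Effector programs in HC donors moved mostly in one direction. Of the 25 measured cytotoxic genes 24 rose, and 24 also when adjusted over the list alone, with a median of 5.13 (adjusted p = 1.58e-31), unchanged with its 2 members without naive counts at their bound. Perforin (PRF1, ENSG00000180644, chromosome 10, 70597348 to 70602775) rose by 3.99 ± 0.26, from 13.8 ± 4.39 to 220 ± 75.5 CPM (SD, n = 7), and granzyme A (GZMA) by 5.37 ± 0.38. Among homing and residency genes 19 of 21 rose (20 adjusted over the list alone, median 2.31, adjusted p = 1.44e-15), including the integrin chains ITGAL (1.16 ± 0.11) and ITGB2 (1.00 ± 0.12). Terminal differentiation genes rose in 9 of 15 cases (12 adjusted over the list alone, median 2.63, adjusted p = 3.26e-07), among them ZEB2 (4.49 ± 0.54), a repressor tied to effector fate, and the cell cycle inhibitor CDKN1A (5.17 ± 0.68). The naive and stem-like list fell, with 15 of 21 members lower and 1 higher (the same counts adjusted over the list alone, median -0.87, adjusted p = 1.22e-21). Its members ACTN1, LEF1 and CCR7, the last of which directs cells to lymph nodes and was a sorting marker, were lower by -3.26 ± 0.15, -2.04 ± 0.13 and -2.66 ± 0.16. TCF7, which encodes the self-renewal factor TCF-1, fell by 0.87 ± 0.12, from 1035 ± 100 to 567 ± 116 CPM.

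The lists that name T cell exhaustion also moved between the subsets of healthy donors. Of 21 exhaustion transcription factors 15 rose (16 adjusted over the list alone, median 1.63, adjusted p = 1.39e-16), with TBX21 at 5.45 ± 0.24, BHLHE40 at 4.65 ± 0.37, ID2 at 1.63 ± 0.19 and TOX (ENSG00000198846, chromosome 8, 58805418 to 59119208) at 2.59 ± 0.56. Among 21 inhibitory receptors 6 rose and 1 fell (8 and 1 adjusted over the list alone), and the median was 0.26 (adjusted p = 0.0429). That call was lost at adjusted p = 0.202 with an estimated correlation, and at 0.0581 (median 0.47) without the experienced HC library with the fewest genes. PDCD1, which encodes the checkpoint receptor PD-1 (ENSG00000188389, chromosome 2, 241849881 to 241858908), rose by 6.11 ± 1.10, from 0.138 ± 0.366 to 8.62 ± 5.00 CPM. It rose by 4.82 in series A and had no count in naive HC cells of series B. The size of the pooled fold therefore rests on very few naive counts. LAG3 rose by 4.40 ± 0.63, TIGIT by 3.52 ± 0.49 and KLRC1, which encodes NKG2A, by 2.88 ± 0.49. KLRC1 did not pass with limma voom (adjusted p = 0.136) or in series B (0.111), nor TOX in series A (0.0676), with lowest values over the alternatives of 3.85e-14 and 3.62e-08. CD8A rose by 0.77 ± 0.15.

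Stimulus and stress programs were higher in experienced HC cells too. AP-1 and immediate early genes rose in 27 of 31 cases (27 adjusted over the list alone, median 1.40, adjusted p = 2.04e-22), such as KLF6 (1.95 ± 0.14) and the phosphatase DUSP5 (4.46 ± 0.35). NF-kB and TNF response genes rose in 18 and fell in 2 of 28 cases (19 and 2 adjusted over the list alone, median 0.89, adjusted p = 1.52e-07). Interferon gamma response and antigen presentation genes rose in 18 and fell in 1 of 26 (20 and 1 adjusted over the list alone, median 0.69, adjusted p = 9.96e-10), with the class II chaperone CD74 at 1.78 ± 0.11 and the immunoproteasome gene PSMB9 at 1.10 ± 0.15. Unfolded protein response genes rose in 17 of 24 (17 up and 2 down adjusted over the list alone, median 0.83, adjusted p = 1.61e-13), including the chaperone genes PDIA6 (1.64 ± 0.14) and HYOU1 (1.31 ± 0.14). Apoptosis genes rose in 13 and fell in 1 of 27 (15 and 2 adjusted over the list alone, median 0.57, adjusted p = 1.51e-05), with the death receptor FAS at 2.89 ± 0.22 and the initiator caspase CASP10 at -1.43 ± 0.15. Cytokine receptor and STAT genes rose in 14 and fell in 5 of 33 (15 and 5 adjusted over the list alone, median 0.16, adjusted p = 0.00164), with IL2RB, a receptor chain for IL-2 and IL-15, at 2.19 ± 0.22.

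Metabolic and growth lists in HC were also tested. Glycolysis genes rose in 14 and fell in 2 of 26 (15 and 2 adjusted over the list alone, median 0.48, adjusted p = 0.00243). The glycolysis list stood at adjusted p = 0.0880 with an estimated correlation. GAPDH stood at 1.11 ± 0.12 and PDK1 at -2.89 ± 0.15. Ribosomal protein genes fell in 13 of 75 (11 adjusted over the list alone, median -0.19, adjusted p = 0.00193), such as RPL22 (-0.60 ± 0.13) and RPL9 (-0.44 ± 0.11). That list stood at adjusted p = 0.654 with an estimated correlation and had medians of -0.06 in series A and -0.27 in series B. Proliferation genes (5 of 27 higher, 4 adjusted over the list alone, median 0.69, adjusted p = 0.0208) stood at adjusted p = 0.488 with an estimated correlation. Oxidative stress genes (9 of 22 higher, 12 up and 1 down adjusted over the list alone, median 0.40, adjusted p = 0.00207) stood at adjusted p = 0.110 with an estimated correlation. The 8 program lists that did not pass were type I interferon (adjusted p = 0.0802), heat shock (0.25), nuclear-encoded oxidative phosphorylation (0.261), mitochondrially encoded (0.874), fatty acid oxidation (0.946), TCA cycle (0.347), T cell receptor signalling (0.249), and chromatin regulators (0.249). Within the last list the DNA methyltransferase DNMT3A fell by 1.07 ± 0.11, and the TCA cycle gene OGDH rose by 1.46 ± 0.12. The TCA cycle list had a median of -0.04 with a positive mean (0.06) and test.

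Markers of unconventional and other lymphocytes rose with experience in HC donors. The MAIT cell list rose in 9 of 10 genes (10 adjusted over the list alone, median 5.10, adjusted p = 2.74e-10), with the cytokine receptor chain IL18RAP at 5.98 ± 0.49 and the MAIT receptor segment TRAV1-2 at 2.56 ± 0.39. The gamma delta list rose in 4 of 6 (4 adjusted over the list alone, median 3.15, adjusted p = 1.77e-11), with TRGC1 and TRGC2, constant genes of the gamma receptor chain, at 3.0 ± 0.20 and 3.30 ± 0.23. The NK cell list rose in 8 and fell in 1 of 10 (8 and 1 adjusted over the list alone, median 2.24, adjusted p = 1.01e-05), and cytotoxic T cells share many of its genes. The CD4 T cell list rose in 4 and fell in 1 of 10 (6 and 1 adjusted over the list alone, adjusted p = 0.0132; adjusted p = 0.132 with an estimated correlation), with CD40LG at 4.44 ± 0.81 and CCR4 at 5.06 ± 0.81. The regulatory T cell list rose in 4 of 7 (6 adjusted over the list alone, adjusted p = 0.000706; adjusted p = 0.0607 with an estimated correlation). TRDC, FOXP3 and CD4 averaged 0.935 ± 1.02, 2.92 ± 1.42 and 0.675 ± 0.556 CPM in naive HC. In experienced HC they averaged 3.49 ± 5.04, 3.93 ± 2.39 and 1.63 ± 1.79. The gamma delta, regulatory and CD4 T cell lists therefore do not by themselves show more cells of these kinds. B cell and monocyte lists did not pass (adjusted p = 0.986 and 0.647). In HC, 21 lists passed with the preset and 14 with an estimated correlation.

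In ME donors the same comparison asked whether the step from naive to experienced cells runs alike in disease. LTK rose by 7.56 ± 0.84 (log2, ± SE, 7 libraries per subset), ZNF683, which encodes the residency factor Hobit, by 6.78 ± 0.89, KLRB1 by 6.40 ± 0.69 and TNF by 6.34 ± 1.34. PLEKHG3, DLG5 and the neuropeptide receptor NMUR1 rose by 6.40 ± 0.95, 6.25 ± 1.01 and 6.24 ± 0.90. Falls were led by NRCAM (-6.97 ± 0.81), NOG (-5.52 ± 0.97), the guidance receptor ROBO1 (-5.27 ± 1.10), SFRP5 (-4.79 ± 1.14), SHANK1 (-4.78 ± 0.81), EDAR (-4.72 ± 0.46), ADD2 (-4.63 ± 0.76) and CACHD1 (-4.57 ± 0.59). These genes moved the same way in 7 of 7 donors, except TNF, which was higher in 6. LTK did not pass with limma voom (adjusted p = 0.113, the highest of its alternatives, against a lowest of 1.34e-23). In series A alone, with 3 donors, NMUR1, NOG, ROBO1, SFRP5, SHANK1 and ADD2 did not pass (adjusted p from 0.0530 for NMUR1 to 0.451 for SFRP5). In total 2275 of 16310 genes passed (13.9%), with 1385 higher, 890 lower and 1182 changed by more than 2-fold. Series A alone gave 388 genes, series B alone 1502, and limma voom with sample weights 3624. Without the 2 marked libraries 3039 of 18668 genes passed, and without the naive library with the highest cytotoxic mean 2077 of 16793. Whether the step is smaller in ME than in HC cannot be read from these counts.

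Effector and exhaustion lists moved in ME donors as follows. Cytotoxic genes rose in 23 of 24 cases (24 adjusted over the list alone, median 4.66, adjusted p = 6.87e-27), with PRF1 at 3.65 ± 0.31, GZMA at 4.91 ± 0.54, the granule proteoglycan SRGN at 1.99 ± 0.27 and GZMB at 4.62 ± 1.22 (adjusted p = 0.0251). For GZMB in experienced vs naive in ME the adjusted p ran from 0.000325 with the DESeq2 Wald test to 0.110 with limma voom. Exhaustion transcription factors rose in 15 of 21 (17 adjusted over the list alone, median 1.76, adjusted p = 2.82e-23), including EOMES at 3.73 ± 0.29, MAF at 6.05 ± 0.43, PRDM1 at 4.81 ± 0.39 and TOX at 3.19 ± 0.64. Inhibitory receptors rose in 6 of 20 (7 adjusted over the list alone, median 0.13, adjusted p = 0.00571), with LAG3 at 4.25 ± 0.40, KLRC1 at 2.50 ± 0.46 and PDCD1 at 4.55 ± 0.86. The naive and stem-like list fell in 12 of 21 (1 up and 15 down adjusted over the list alone, median -1.0, adjusted p = 3.66e-13), with ACTN1 at -3.16 ± 0.25, SATB1 at -1.22 ± 0.15 and CCR7 at -2.55 ± 0.26. TCF7 did not pass at -0.58 ± 0.24 (adjusted p = 0.140, lower in 6 of 7 donors). With donors as a block it stood at -0.73 (adjusted p = 0.0269), and without the 2 marked libraries at -0.93 (adjusted p = 0.000129). Its adjusted p ran from 0.000103 (limma voom) to 0.967 (series A alone) over the alternatives. CD8A did not pass either, at 0.46 ± 0.17 (adjusted p = 0.0739), but passed with no filter (0.00542), with DESeq2 (0.0302), with limma voom (0.0116) and without the marked libraries (0.0323), with a range up to 0.697 over the alternatives.

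Several lists in ME passed with the preset correlation alone. Terminal differentiation genes (7 of 15 higher, 10 adjusted over the list alone, median 1.24, adjusted p = 0.000159, with KLRG1 at 4.09 ± 0.51) stood at adjusted p = 0.0528 with an estimated correlation. AP-1 genes (21 of 32 higher, 24 up and 2 down adjusted over the list alone, median 1.33, adjusted p = 2.05e-17, with RGS1 at 2.84 ± 0.24) stood at adjusted p = 0.0527 with an estimated correlation. NF-kB genes (11 up and 1 down of 28, 17 and 1 adjusted over the list alone, median 0.67, adjusted p = 1.24e-05, with the kinase MAP3K8 at 4.18 ± 0.53) stood at adjusted p = 0.0883 with an estimated correlation. Interferon gamma genes (8 of 26 higher, 11 adjusted over the list alone, median 0.39, adjusted p = 1.15e-05, with CD74 at 1.81 ± 0.19 and HLA-DRA at 4.27 ± 0.73) stood at adjusted p = 0.0991 with an estimated correlation. Unfolded protein response genes (8 of 24 higher, 11 adjusted over the list alone, median 0.53, adjusted p = 8.17e-07, with the stress sensor ERN1 at 3.01 ± 0.23) stood at adjusted p = 0.0949 with an estimated correlation. Ribosomal protein genes (24 of 75 lower, 46 adjusted over the list alone, median -0.45, adjusted p = 3.11e-11, with RPL22 at -0.92 ± 0.18 and RPL4 at -0.66 ± 0.15) stood at adjusted p = 0.285 with an estimated correlation. T cell receptor signalling genes (6 up and 5 down of 33, 8 and 5 adjusted over the list alone, median 0.14, adjusted p = 0.0196) stood at adjusted p = 0.128 with an estimated correlation. Oxidative stress genes (8 of 23 higher, 9 up and 1 down adjusted over the list alone, median 0.18, adjusted p = 0.0436) stood at adjusted p = 0.285 with an estimated correlation. Cytokine receptor genes (11 up and 4 down of 33, 14 and 5 adjusted over the list alone, median 0.25, adjusted p = 0.00750, with IL10RA at 1.92 ± 0.17, IL2RB at 2.15 ± 0.21 and IL6ST at -2.20 ± 0.18) stood at adjusted p = 0.0865 with an estimated correlation.

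Other lists in ME held with both kinds of correlation. Homing genes rose in 15 of 19 (16 adjusted over the list alone, median 1.42, adjusted p = 3.48e-17), with ITGB1 at 2.71 ± 0.35, and apoptosis genes rose in 10 and fell in 2 of 27 (11 and 2 adjusted over the list alone, median 0.58, adjusted p = 0.000169). MAIT markers rose in 8 of 9 (9 adjusted over the list alone, median 4.77, adjusted p = 3.70e-12), with the innate-like factor ZBTB16 at 3.06 ± 0.48. Gamma delta markers rose in 4 of 6 (4 adjusted over the list alone, median 2.90, adjusted p = 1.93e-06), with TRGC2 at 3.08 ± 0.29, NK markers in 8 of 10 (8 up and 1 down adjusted over the list alone, median 2.35, adjusted p = 3.14e-07) and regulatory T cell markers in 3 of 6 (4 adjusted over the list alone, median 2.09, adjusted p = 4.88e-05). The program lists that did not pass were glycolysis (adjusted p = 0.471, with GAPDH at 1.11 ± 0.14 and PDK1 at -2.59 ± 0.17), mitochondrially encoded (0.0698, and 0.0295 without the naive library with the highest cytotoxic mean), type I interferon (0.114), heat shock (0.934), nuclear-encoded oxidative phosphorylation (0.279), fatty acid oxidation (0.934), TCA cycle (0.934), proliferation (0.233) and chromatin regulators (0.934, with DNMT3A at -1.22 ± 0.16). The CD4 T cell list (0.146), B cell list (0.934) and monocyte list (0.934) did not pass. TRDC averaged 0.795 ± 0.713 CPM in naive ME and 1.71 ± 1.96 in experienced ME, and FOXP3 3.05 ± 1.11 and 5.17 ± 4.27. The gamma delta and regulatory T cell lists therefore do not by themselves show more cells of these kinds. The heat shock, TCA cycle, chromatin, fatty acid oxidation, B cell and monocyte lists had a median, mean or test of differing sign. In ME, 19 lists passed with the preset and 10 with an estimated correlation.

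The experienced programs of HC and ME donors overlapped widely. Of the 15564 genes tested in both, 1147 were higher in both and 730 lower in both, where independent lists of those sizes would share 172 and 101, and 0 changed in opposite directions. A further 1843 genes passed in HC alone, of which 1760 (95.5%) had the same sign in ME, and 390 passed in ME alone, of which 383 had the same sign in HC. The log2 fold changes correlated at r = 0.767 across all shared genes and at 0.968 across the 1877 changed in both, where genes are not independent replicates. Genes changed in both had a median absolute change of 1.11 in HC and 1.11 in ME. These genes were chosen for passing in both classes in the same data, so their correlation and sizes are partly set by that choice. A gene past the threshold in one donor class and not in the other is not thereby shown to differ, and the test of that difference is the interaction described last.

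**Figure D2:**
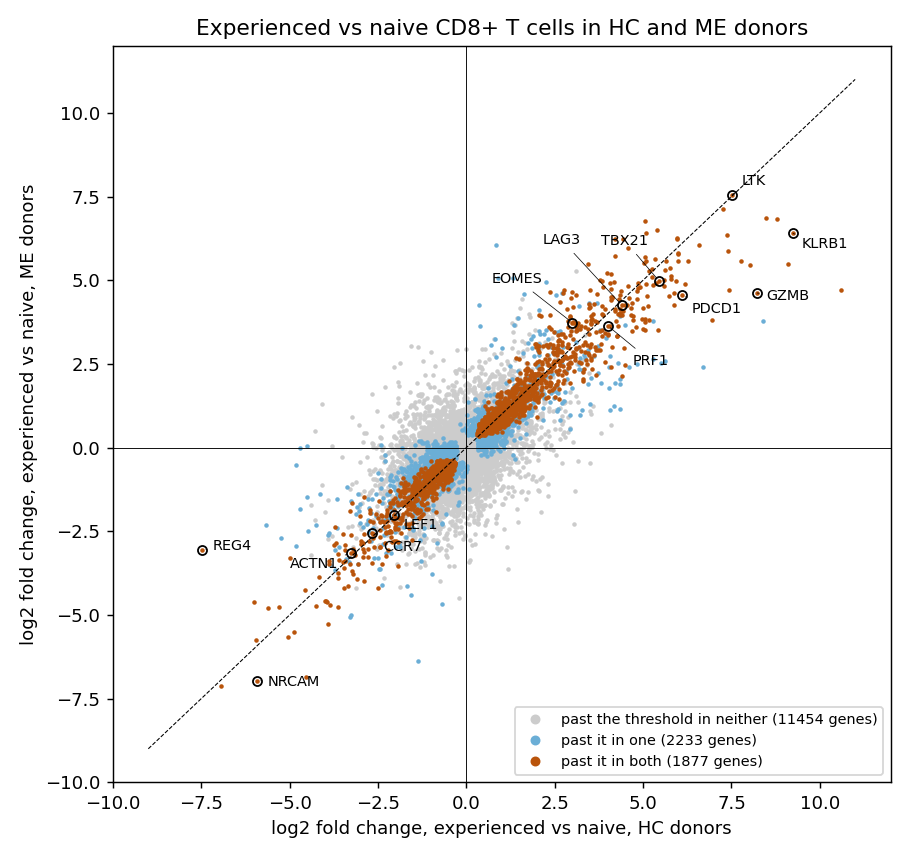
Log2 fold change of experienced against naive cells in HC donors (horizontal axis) and in ME donors (vertical axis) for 15564 genes, coloured by whether the adjusted p was under 0.05 in both, in one or in neither, with the dashed line marking equal values. Of the 1877 genes past the threshold in both, 0 lie in opposite quadrants.

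Naive cells of ME and HC donors were compared to ask whether the disease is visible before antigen contact. No gene passed, and the values with the smallest p were modest. OAS3, an interferon-induced antiviral enzyme, stood 0.81 ± 0.17 higher in ME (log2, ± SE, 7 donors per class), at 59.3 ± 11.9 against 33.3 ± 8.77 CPM (SD, n = 7), and the growth factor gene GDF11 0.80 ± 0.17 higher. ACTN4, an actin crosslinker, stood 0.81 ± 0.19 higher. YOD1, a deubiquitinase, C3orf38 and PGAP1, which remodels GPI anchors, stood at -0.70 ± 0.17, -0.61 ± 0.15 and -0.79 ± 0.20, and none of the 6 passed (adjusted p = 0.634 each). The edgeR test called 0 of 17347 genes, 900 had an unadjusted p under 0.05 (499 higher, 401 lower, 867 expected by chance), limma voom called 0 and DESeq2 called 2. Those 2 were SGK1, a kinase induced by stress and glucocorticoids, and GDF11. OAS3 stood at 0.79 in series A and 0.84 in series B, and GDF11 at 0.74 and 0.87.

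In naive cells 3 lists passed with the preset correlation, all toward ME, and 0 with an estimated correlation or by fry. Cytotoxic genes had a median of 0.45, with 15 of 16 positive and 0 past the threshold over all genes or adjusted over the list alone (adjusted p = 0.00536; adjusted p = 0.666 with an estimated correlation). Among them GZMM stood at 0.43 ± 0.15, GNLY at 1.91 ± 0.71 and KLRD1, which encodes CD94, at 1.66 ± 1.06. The list's median was 0.02 in series A and 1.23 in series B. A single naive ME library had the highest cytotoxic mean (2.91 log2 CPM over all genes of the list, against 1.94 for the next and a median of 0.72 for the other naive libraries), and without it the list stood at 0.20 (adjusted p = 0.146). Interferon gamma response and antigen presentation genes had a median of 0.22 (22 of 26 positive, 0 higher over all genes, 1 higher adjusted over the list alone, adjusted p = 3.45e-06; adjusted p = 0.366 with an estimated correlation), with TAPBP, a peptide-loading chaperone, at 0.58 ± 0.15 and the immunoproteasome genes PSMB8 and PSMB9 at 0.51 ± 0.17 and 0.43 ± 0.16. Without the same library it stood at 0.17 (adjusted p = 0.000115), in series A at 0.41 and in series B at 0.15 (adjusted p = 0.616). AP-1 genes had a median of 0.19 (20 of 30 positive, 0 higher over all genes, 1 higher adjusted over the list alone, adjusted p = 0.0252; adjusted p = 0.761 with an estimated correlation), with SGK1 at 1.26 ± 0.27, EGR1 at 0.83 ± 0.28 and DUSP5 at 1.00 ± 0.49. Its median was 0.17 in series A (adjusted p = 0.000236) and 0.06 in series B (adjusted p = 0.861), and without the same library it stood at adjusted p = 0.126.

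The exhaustion lists did not pass in naive cells. Inhibitory receptors had a median of 0.19 (0 of 19 past the threshold over all genes, 0 adjusted over the list alone, adjusted p = 0.406), with BTLA at 0.63 ± 0.31 and CD38 at -0.58 ± 0.34. Exhaustion transcription factors had a median of -0.07, a mean of 0.05 and a negative test (0 of 19 past the threshold over all genes, 0 adjusted over the list alone, adjusted p = 0.903). TOX stood at -0.15 ± 0.73, TCF7 at 0.08 ± 0.10, CCR7 at 0.06 ± 0.12 and CD8A at 0.24 ± 0.15, while PDCD1 and GZMB were below the count filter. The naive and stem-like list had a median of 0.03 (adjusted p = 0.675). The label series disagreed on the ribosomal protein list, with a median of 0.35 in series A and -0.39 in series B, on the mitochondrially encoded list, with 0.51 and -0.43, and on the nuclear-encoded oxidative phosphorylation list, with 0.14 (adjusted p = 0.00110) and -0.20 (adjusted p = 8.9e-05). Pooled, these stood at -0.03 (adjusted p = 0.398), 0.02 (adjusted p = 0.826) and 0.01 (adjusted p = 0.789). The remaining program lists had medians between 0.01 and 0.13 and did not pass, and among them homing, oxidative phosphorylation, fatty acid oxidation and proliferation had a median, mean or test of differing sign. The B cell list did not pass either (median 0.94, adjusted p = 0.0868).

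Experienced cells of ME and HC donors were compared to ask whether antigen-experienced CD8+ T cells in ME carry an exhaustion program. No gene passed here either. EOMES, a T-box factor of memory and exhausted T cells (ENSG00000163508, chromosome 3, 27715949 to 27722711), stood 1.11 ± 0.22 higher in ME (log2, ± SE, 7 donors per class), at 98.5 ± 28.6 against 46.6 ± 16.5 CPM (SD, n = 7). CCR4, a skin-homing receptor of memory T cells (ENSG00000183813, chromosome 3, 32951574 to 32956349), stood at -1.32 ± 0.26, with 23.5 ± 9.48 against 57.3 ± 33.2 CPM, and CSGALNACT1, an enzyme of chondroitin sulphate synthesis, at -1.23 ± 0.25. Each of the 3 had an adjusted p of 0.365. DTHD1 (1.06 ± 0.25), PON2 (1.30 ± 0.32) and EPSTI1, an interferon-induced gene (-1.17 ± 0.27), had adjusted p = 0.786. The edgeR test called 0 of 16397 genes, 866 had an unadjusted p under 0.05 (455 higher, 411 lower, 820 expected by chance), limma voom called 1 (CCR4) and DESeq2 called 10, among them EOMES, CCR4, CSGALNACT1 and EPSTI1. EOMES stood at 1.16 in series A and 1.07 in series B, and CCR4 at -1.0 and -1.63.

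Checkpoint and exhaustion genes were compared between experienced ME and HC cells, and no single gene passed. Inhibitory receptors had a median of 0.11 (0 of 20 past the threshold over all genes, 0 adjusted over the list alone, adjusted p = 0.237), with CD244 at 0.70 ± 0.25, TIGIT at 0.54 ± 0.26, CTLA4 at -0.78 ± 0.38 and PDCD1 at 0.11 ± 0.40 (9.34 ± 4.47 against 8.52 ± 4.93 CPM). The exhaustion transcription factors passed with the preset correlation (median 0.08, 14 of 21 positive, 0 over all genes, 2 higher adjusted over the list alone, adjusted p = 0.0321; adjusted p = 0.243 with an estimated correlation). The 2 were EOMES and IKZF3, which encodes Aiolos (0.61 ± 0.17), and TBX21 stood at 0.53 ± 0.20. The list's median was 0.25 in series A and 0.01 in series B. TOX stood at 0.33 ± 0.33 (1.04 in series A and -0.38 in series B), TCF7 at 0.36 ± 0.27, CCR7 at 0.09 ± 0.29, GZMB at 0.12 ± 0.73 and CD8A at -0.11 ± 0.17. The naive and stem-like list did not pass (median 0.12, adjusted p = 0.641).

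Translation and respiration genes gave the lowest list p-values in experienced cells, toward lower values in ME. Of 75 ribosomal protein genes 4 were positive, the median was -0.36, 0 passed over all genes and 32 were lower adjusted over the list alone (adjusted p = 8.38e-27; adjusted p = 0.243 with an estimated correlation). RPL8, RPL13 and RPL10A stood at -0.53 ± 0.15, -0.54 ± 0.16 and -0.48 ± 0.15, and the list at -0.33 in series A and -0.39 in series B. The exact permutation test of the list's mean gave a difference of -0.38 (p = 0.00524), which did not pass at adjusted p = 0.173. Nuclear-encoded oxidative phosphorylation genes had a median of -0.24 (12 of 78 positive, 0 passing either way of adjustment, including adjusted over the list alone, adjusted p = 6.78e-08; adjusted p = 0.243 with an estimated correlation), with ATP5MC1 at -0.82 ± 0.23, COX7C at -0.56 ± 0.16 and ATP5F1A at -0.45 ± 0.14. Its medians were -0.23 and -0.33 in the series. Mitochondrially encoded genes went the other way, at a median of 0.47 with 13 of 13 positive (0 over all genes or adjusted over the list alone, adjusted p = 0.000132; adjusted p = 0.574 with an estimated correlation), with MT-ND5 at 0.81 ± 0.35 and MT-CO1 at 0.54 ± 0.29. That list stood at 1.03 in series A, at -0.04 in series B, at 0.01 (adjusted p = 0.850) without the 2 marked ME libraries, and at 0.04 without the 1 of them with 21.2% of counts in these genes.

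A further 5 lists passed in experienced cells with the preset correlation, and none of the 9 passed with an estimated correlation or by fry. Cytotoxic genes had a median of 0.21 (20 of 25 positive, 0 over all genes or adjusted over the list alone, adjusted p = 0.0267; adjusted p = 0.626 with an estimated correlation), with CCL5 at 0.60 ± 0.31, CX3CR1 at 1.14 ± 0.62 and CST7 at 0.39 ± 0.20. Their median was 0.51 in series A and 0.04 in series B. The CD4 T cell list had a median of -0.65 (0 over all genes, 1 of 9 lower adjusted over the list alone, which was CCR4, adjusted p = 0.00111; adjusted p = 0.243 with an estimated correlation). CD4 itself averaged 1.63 ± 1.79 CPM in HC and 0.306 ± 0.430 in ME. Chromatin regulators had a median of 0.10 (0 of 30 over all genes or adjusted over the list alone, adjusted p = 0.00892; adjusted p = 0.243 with an estimated correlation), with ARID1A at 0.40 ± 0.14 and the demethylase gene KDM6B at 0.53 ± 0.18. Glycolysis genes had a median of -0.18 (0 of 26 over all genes or adjusted over the list alone, adjusted p = 0.0317; adjusted p = 0.574 with an estimated correlation), with HK1 at -0.33 ± 0.14 and PKM at -0.28 ± 0.12. Unfolded protein response genes had a median of -0.13 (0 of 24 over all genes or adjusted over the list alone, adjusted p = 0.0267; adjusted p = 0.575 with an estimated correlation). Without the 2 marked libraries 4 of the 9 lists passed (ribosomal proteins, oxidative phosphorylation, CD4 T cell and exhaustion transcription factors), and the regulatory T cell list passed in addition (median -0.79, adjusted p = 0.0112, against -0.54 and 0.0735 with them). The mitochondrially encoded list, the cytotoxic list (median 0.28, adjusted p = 0.126), glycolysis (-0.12, adjusted p = 0.168), chromatin regulators (adjusted p = 0.0976) and the unfolded protein response (-0.02, adjusted p = 0.550) did not. The NK cell list did not pass (median 0.21, adjusted p = 0.270), with KLRF1 at 1.14 ± 0.35 (adjusted p = 0.786, and its 1 member that was higher adjusted over the list alone). The MAIT list did not pass (median -0.40, adjusted p = 0.237) and stood at -1.82 in series A and 0.80 in series B. The gamma delta list had a median of -0.44 with a positive camera test (adjusted p = 0.993). The proliferation list stood at -0.29 (adjusted p = 0.0520), and the homing and type I interferon lists had a median, mean or test of differing sign and did not pass (adjusted p = 0.941 and 0.768).

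**Figure D3:**
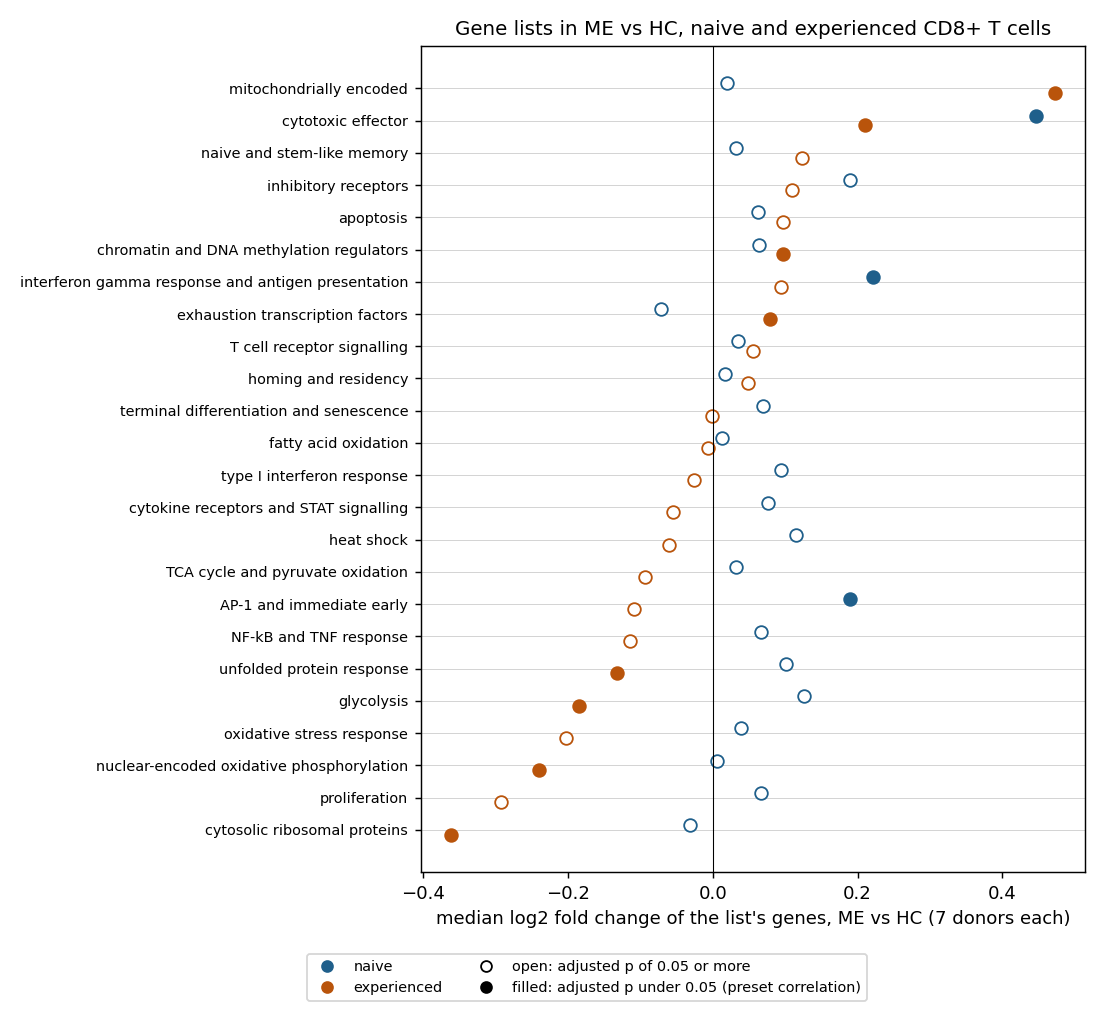
Median log2 fold change of ME against HC donors (horizontal axis, 7 donors per class) for 24 program lists in naive and in experienced cells, filled where the adjusted p with the preset correlation was under 0.05. The ribosomal protein list lies at -0.36 in experienced and -0.03 in naive cells, and the mitochondrially encoded list at 0.47 and 0.02.

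The interaction asked whether the ME effect differs between experienced and naive cells. No gene passed. Positive values, toward a larger ME minus HC difference in experienced cells, began in order of p with REG4 (4.11 ± 1.20, log2 ± SE, 28 libraries), CENPV (0.94 ± 0.31) and IKZF3 (0.59 ± 0.20), and negative values in order of p with ACTN4 (-0.88 ± 0.22), DENND5A (-0.85 ± 0.24) and NOSIP (-0.79 ± 0.23). GZMB stood at -3.77 ± 1.56, GNLY at -2.51 ± 1.06, PDCD1 at -1.45 ± 1.32, TOX at 0.52 ± 0.86, TCF7 at 0.23 ± 0.28, CCR7 at 0.02 ± 0.33 and CD8A at -0.38 ± 0.23. The pooled values of GZMB and PDCD1 rest on series B, where neither had a count in naive HC cells and the fitted values are therefore not given. In series A they stood at -0.28 and 0.04. The edgeR test called 0 of 21902 genes (smallest adjusted p 0.358), 745 had an unadjusted p under 0.05 (276 positive, 469 negative, 1095 expected by chance), and DESeq2 and limma voom called 0. CCL4 had no count in naive HC cells, so its fitted interaction is not given.

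Among lists 9 passed in the interaction with the preset correlation and 0 with an estimated one. Lower values of the ME effect in experienced than in naive cells were seen for the cytotoxic (median -0.65, adjusted p = 0.00141), interferon gamma (-0.29, adjusted p = 0.0168), AP-1 (-0.23, adjusted p = 0.00397), NF-kB (-0.25, adjusted p = 0.00397), unfolded protein response (-0.24, adjusted p = 0.00384), oxidative phosphorylation (-0.30, adjusted p = 8.71e-05) and ribosomal protein lists (-0.35, adjusted p = 4.29e-13), each at adjusted p = 0.639 with an estimated correlation. Glycolysis stood at -0.29 (adjusted p = 0.000924; adjusted p = 0.532 with an estimated correlation). Mitochondrially encoded genes had a median of 0.42 (adjusted p = 0.00427; adjusted p = 0.639 with an estimated correlation), and -0.03 without the 2 marked libraries. Within these 9 lists 0 members passed over all genes and 0 adjusted over the list alone. The ribosomal protein list stood at -0.68 in series A and -0.02 in series B, and the cytotoxic list at -0.10 and -1.11. Without the single naive ME library with the highest cytotoxic mean the cytotoxic list stood at -0.21 (adjusted p = 0.109) and the interferon gamma list at -0.18 (adjusted p = 0.109), so neither passed. Inhibitory receptors (median -0.24, adjusted p = 0.871) and exhaustion transcription factors (median 0.10, adjusted p = 0.211) did not pass, though the latter stood at 0.22 (adjusted p = 0.0341) without that library.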

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

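The tests of the marked libraries, of the ribosomal and cytotoxic medians over donor splits, and the fits that leave libraries out were chosen after the results were seen; the splits that count genes and lists, the matched-gene test and the test for experienced cells in the naive gate were written down before their own results. A library was picked out when it lay far from the other 6 of its group, by the ratio of its gap to the range of the 7 values. Chance gives about 1 in 20 such sets, so 7.4 of the 148 tested, and 14 were found. Among experienced HC libraries, 1 was lowest for the B cell list (mean log2 CPM -0.95, next 0.10), 1 for glycolysis (5.23, next 5.73) and 1 for the platelet list (-3.06, next -0.62), and 1 was highest for type I interferon genes (5.32, next 4.86). Among experienced ME libraries, 1 was highest for the share of mitochondrially encoded counts (21.2%, next 6.61%), for the share of the 20 largest genes (24.7%, next 14.1%) and for the mitochondrially encoded list (13.05, next 11.42). Among naive HC libraries, 1 was lowest for total counts (10.1 in units of 1e6, next 17.7), 1 for T cell receptor signalling (7.26, next 7.40) and 1 for the monocyte list (-1.88, next -1.11), and 1 was highest for interferon gamma genes (5.63, next 5.34). Among naive ME libraries, 1 was highest for genes with a count (30174, next 23444), 1 lowest for the mitochondrially encoded list (10.48, next 10.99) and 1 highest for oxidative phosphorylation (5.09, next 4.69).

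The ME effect differed between experienced and naive cells, with the preset correlation, for 9 lists. Their medians were -0.65 for cytotoxic, -0.29 for interferon gamma, -0.23 for AP-1, -0.25 for NF-kB, -0.24 for unfolded protein response, -0.29 for glycolysis, -0.30 for oxidative phosphorylation, 0.42 for mitochondrially encoded and -0.35 for ribosomal protein genes. Each of the 9 was lost with an estimated correlation, and 25 of 100 splits of the donors, the real one included, gave as many lists (highest other split 17), so chance cannot be excluded.

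Ribosomal protein genes were lower in experienced ME cells at a median of -0.36, and 3 accounts were weighed. The 2 marked libraries do not account for it, as the median without them was -0.33. Loss of short, highly expressed transcripts could account for a part or for all of it. Unlisted genes matched in length, GC content and level stood at -0.14. The median after subtracting them was -0.23 (SE 0.02 over 75 genes, which does not cover the spread between donors). The length used, with a median of 3002 for the ribosomal protein genes, may exceed that of their transcripts. How close the matched genes came to the ribosomal protein genes in length and level is also not shown. The subtraction therefore does not show how large a part such a loss could hold. Chance stays open, since 1 of 100 splits, the real one, lay as far from 0 (highest other 0.32), while the list was singled out afterwards and its exact permutation p was 0.173 after adjustment. A lower translation program in ME or a difference in handling between donor classes could also hold, and no value here separates these.

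Mitochondrially encoded genes were higher in experienced ME cells at a median of 0.47, and this goes with 1 of the 2 marked libraries. The median was 0.00925 without both, 0.0379 without the one in which these genes took 21.2% of counts, and 0.49 without the other, which had 5.96%. The meaning of the mark is not given in the sources used here. Damaged or stressed cells in that 1 library would raise the share of mitochondrial RNA, and a biological difference of that sample would do so as well. The values cannot tell these apart.

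Cytotoxic genes were higher in naive ME cells at a median of 0.45, with the highest mean in 1 naive ME library. If experienced cells had entered its sort gate, other genes high in experienced cells should be raised alike, and 62 unlisted ones implied 7.76% of experienced RNA there, against 10.5% from 16 cytotoxic genes and at most 2.28% in the other 13 naive libraries. This fits experienced cells in the gate, and memory cells that keep the naive surface markers would look the same. The test does not show by which route experienced RNA came into this library. Another source, such as the experienced libraries whose run of numbers it shares, was not tested. This library is also 1 of the 2 whose match to a column is less sure. The other is the experienced library of the same donor. Their cytotoxic means were 2.91 and 5.55 log2 CPM and their naive and stem-like means 7.92 and 6.57, each on the side of its own subset. These values argue against a swap of the 2. Over donor splits 41 of 100, the real one included, gave a cytotoxic median as far from 0 (highest other 1.35). The exact permutation test of the list's mean gave a difference of 0.86 (p = 0.0140), which did not pass at adjusted p = 0.231. Chance is therefore not excluded for the ME difference.

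Other splits of the donors showed what chance can do. For experienced vs naive cells the 100 splits were of libraries, so both libraries of a donor could fall on the same side. For ME vs HC in naive cells 74 of 100, the real one included, gave at least the 3 lists found (highest other 16), and in experienced cells 26 gave at least the 9 lists (highest other 13), so chance cannot be excluded for either. For genes the real count was 0 in both and in the interaction, which all 100 splits reach by construction, so the splits test nothing there (highest other 6, 16 and 1). For experienced vs naive cells only the real split, 1 of 100, reached its count, with 3750 genes in HC (highest other 1222) and 2275 in ME (highest other 346). Among 64 splits that keep 1 library of each donor on either side, as the real one does, the highest other gave 372 and 297. Chance is therefore an unlikely account of these gene counts, as the real split stood first of 64 in each class. The number of lists does not set the real split apart: it gave 21 in HC and 19 in ME, and others up to 24 and 23. Each other split among the 64 exchanges the libraries of some donors only, so part of the real difference stays in it.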

How the results depend on the processing

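The fits without the 2 marked libraries, without the 3 experienced libraries with the fewest genes, without the experienced HC one of these, and without the naive library with the highest cytotoxic mean were chosen after seeing the data (the 2 marked libraries are among the 3, so these fits are not independent), as was the exact permutation of donors; the others were planned. Most gene results kept their direction and side of the threshold: 552 of the named gene values in experienced vs naive in HC did so, with 18 weaker and 6 reversed, and 546 in ME, with 32 weaker and 11 stronger. For ME vs HC, 169 kept them in naive cells (5 stronger, 2 reversed) and 268 in experienced cells (15 stronger, 12 reversed). For the interaction 143 kept them (11 reversed). No gene had passed in these 3 main fits, so a kept value there means only the same sign and again no pass. These counts are therefore no sign of a stable ME effect. Of the list values, 158 and 157 stayed the same for experienced vs naive in HC and ME (10 and 14 weaker), 14 and 43 for ME vs HC in naive and experienced cells (7 and 25 weaker), and 61 for the interaction (26 weaker). With an estimated correlation, by fry and by exact permutation 0 lists passed in ME vs HC in naive cells, in ME vs HC in experienced cells and in the interaction, and with an estimated correlation 10 passed in experienced vs naive in ME. The construction shows the cause in part: the preset assumes a correlation of 0.01 between genes. For every other change given here the cause was not tested.

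Counts of genes moved as follows. ME vs HC in naive cells gave 12 genes with no filter and 2 with DESeq2, against 0. ME vs HC in experienced cells gave 36 with no filter, 10 with DESeq2, 1 with limma voom, 1 in series B and 1 without the 3 libraries with the fewest genes, against 0. Experienced vs naive in HC gave 1983 in series A and 1528 in series B, against 3750. In ME it gave 3624 with limma voom, 3039 without the marked libraries, 388 in series A and 1502 in series B, against 2275. In the single series the number of donors is smaller. The interaction gave 1 gene in series A, against 0. Lists past the threshold in naive cells numbered 10 in series A, 5 in series B and 1 without the library with the highest cytotoxic mean, against 3. In experienced cells 5 passed in series B and 5 without the marked libraries, against 9. For the interaction 3 passed in series B, 5 without the marked libraries and 4 without the 3 with the fewest genes, against 9.

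These lists changed direction in their median or their test. In experienced ME vs HC, the cytotoxic list stood at 0.0436 in series B with a negative test, and the mitochondrially encoded list at -0.0433 in series B, at 0.00925 with a negative test without the marked libraries and at -0.0403 without the 3 with the fewest genes. In the interaction the mitochondrially encoded list stood at -0.0298 without the marked libraries and -0.0425 without the 3, and the ribosomal protein list at -0.0231 in series B with a positive test. Where a test is named here, the median kept its sign and only the test turned. The cause was not tested.

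These genes, none past the threshold, changed sign. In naive ME vs HC, series B gave 0.48 for TOX and -0.0720 for CCR7. In experienced ME vs HC, series B gave -0.15 for MT-CO1, -0.13 for PDCD1, -0.38 for TOX, -0.24 for CCR7 and -0.67 for GZMB, and limma voom gave -0.0620 for PDCD1 and -0.0927 for CCR7. Without the marked libraries TCF7 stood at -0.0552 and CCR7 at -0.0788, and without the 3 with the fewest genes TCF7 at -0.0906, CCR7 at -0.18 and GZMB at -0.0846. In the interaction, PDCD1 stood at 0.0371 in series A, TOX at -0.88, TCF7 at -0.0770 and CCR7 at -0.19 in series B, and CCR7 at -0.0454 with limma voom and -0.0194 with no covariate. Without the marked libraries the interaction was -0.12 for TCF7 and -0.10 for CCR7, and without the 3 it was -0.14 and -0.20. PTPRC in experienced vs naive in HC, at -0.01, stood at 0.00789 with DESeq2 size factors, 0.00793 with DESeq2, 0.0562 with no filter, 0.0284 in series A, 0.0561 in series B and 0.0643 without the experienced HC library with the fewest genes. The cause was not tested.

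These named genes no longer passed in experienced vs naive. In HC they were KLRB1, GZMB, GNLY, LTK, KRT73 and KLRC1 with limma voom, TOX (adjusted p = 0.0676), RPL22 (0.143), RPL9 (0.278), CCR4 (0.0845) and CD8B (0.0720) in series A, and KLRC1 (0.111), PSMB9 (0.0559), RPL9 (0.0804), MS4A1 (0.436), BLK (0.296) and CD8B (0.176) in series B. In ME they were LTK, GZMB and BLK (0.0821) with limma voom, SFRP5 (0.0511) and GZMB with no filter, GZMB in series B and without the marked libraries, and in series A NMUR1, NOG (0.226), ROBO1 (0.291), SFRP5, SHANK1, ADD2 (0.138), PDCD1 (0.180), TOX (0.257), GZMB (0.107), KLRG1 (0.0967), HLA-DRA (0.180), RPL22 (0.102), RPL4 (0.230), ZBTB16 (0.164), MS4A1 (0.0984), BLK (0.393) and CD8B (0.152). All kept their direction, series A and B hold fewer donors, and for the others the cause was not tested.

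With donors as a block for the paired libraries, 135 of 137 named gene results kept their side and direction, and 4226 genes passed in HC, 2430 in ME and 0 in the interaction. The interaction of CCR7 was -0.0387 with the block. TCF7 in experienced vs naive in ME passed at -0.73. Depth limits the rest: genes below the filter, such as PDCD1 and GZMB in naive cells, were not tested for ME vs HC there.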

Other observations

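The genes given here were chosen after their values were seen, and so was the test of the correlation between cell subsets. The related actin crosslinkers ACTN4 and ACTN1 moved in opposite directions with antigen experience. ACTN4 (ENSG00000130402, chromosome 19, 38647649 to 38731583) rose by 3.40 ± 0.14 in HC and 2.60 ± 0.19 in ME (log2 ± SE, 7 libraries per subset), from 19.5 ± 3.96 to 205 ± 23.1 CPM (SD, n = 7) in HC, while ACTN1 fell by 3.26 ± 0.15 and 3.16 ± 0.25. HNRNPLL, a splicing regulator that switches CD45 between its isoforms, rose by 3.10 ± 0.16 in HC and 2.97 ± 0.22 in ME, while the gene of CD45 itself, PTPRC, stood at -0.01 ± 0.10 (adjusted p = 0.953) and 0.23 ± 0.14 (adjusted p = 0.332). CD8B, the second chain of the CD8 co-receptor, fell by 0.78 ± 0.21 and 0.98 ± 0.20, while CD8A stood at 0.77 ± 0.15 and 0.46 ± 0.17. Genes known from B cells parted: MS4A1, which encodes CD20, rose by 4.66 ± 1.28 and 4.16 ± 0.76 and the kinase gene BLK by 3.68 ± 0.75 and 2.93 ± 0.69, while CD79A fell by 2.45 ± 0.34 and 2.98 ± 0.40. MS4A1 and BLK did not pass in HC in series B (adjusted p = 0.436 and 0.296) or in ME in series A (0.0984 and 0.393), and BLK in ME not with limma voom (0.0821). CD8B passed in neither series alone in HC (0.0720 and 0.176), nor in series A in ME (0.152).

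A hypothesis was that ME shifts naive and experienced cells alike. Across 10289 genes the ME minus HC differences of the subsets correlated at r = 0.186, where genes are not independent. As many as 41 of 100 donor splits, the real one included, gave a correlation as high (highest other 0.282, median of the others 0.172), as libraries of the same donors share donor effects, so the hypothesis gained no ground.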
